A study of Rattus norvegicus with 15 samples.

How the data were processed

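Neurons of 2 rat midbrain regions, the substantia nigra pars compacta (SNc) and the ventral tegmental area (VTA), were cut out of tissue by laser capture microdissection, per the labels, and total RNA was profiled on an Affymetrix rat expression array. The labels give 8 SNc arrays, numbered 1 to 8, and 7 VTA arrays, numbered 1 to 6 and 8. They do not say whether a number marks an animal, how many animals were used, or how neurons were recognised before capture. The p-values therefore measure the spread between these arrays, which may in part be technical, and if captures from 1 animal were spread over several arrays the p-values are too small.

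The deposited table holds 1 intensity per probe set and array on a linear scale. A probe set is a group of short probes against 1 transcript. The deposited intensities had a 2% trimmed mean of 150.2 on each of the 15 arrays, so by their values the authors had scaled the arrays to a common level before deposit. The software, background correction and RNA amplification behind the values are not given in the sources used here. No detection calls were used. For arrays, precision is limited by their number. The table held 8799 probe sets, of which 59 control probe sets were left out of the tests. Of the other 8740, the platform annotation gave 7006 a single gene symbol, 308 several and 1426 none, for 4736 different symbols. Gene identifiers of 6985 probe sets were found in the rat gene table of assembly GRCr8, which changed 0 symbols. That table was used for names only. Probe sets with no symbol or several were tested but are given by probe set ID.

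The deposited scaling was kept. Values were turned into log2(intensity + 16), and the 40% of probe sets with the lowest mean over all arrays were left out, which removed those below a signal of about 26.3. The offset makes the log2 differences of dim probe sets smaller than their true size. The remaining 5244 probe sets were compared between SNc and VTA with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are SNc minus VTA, on the log2(intensity + 16) scale, with limma's standard error (SE). A gene was represented by its probe set with the highest mean over all arrays, which gave 3221 genes. Signals are given as mean ± SD over 8 SNc and 7 VTA arrays.

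A set of 24 gene lists was written before the data were examined, and 23 of them had the 3 tested members that were required. They covered dopamine neuron identity, genes enriched in SNc or VTA in earlier work, neuropeptides and granins, oxidative phosphorylation, glycolysis, proteasome subunits, cytosolic ribosomal proteins, the synaptic vesicle cycle, axon guidance, voltage-gated ion channels, glutamate and GABA receptors, calcium-binding proteins, antioxidant and metal handling, parkinsonism genes, immediate early genes, heat shock and chaperones. They also covered markers of astrocytes, oligodendrocytes, microglia, vessels and blood, GABA neurons, glutamate neurons, and serotonin, noradrenaline and cholinergic neurons. Lists were tested with camera in limma at its preset correlation of 0.01, which sets a list's members against all other genes, with adjustment over the 23 lists. Camera with an estimated correlation, fry and an exact permutation of the list's mean per array were alternatives. Fry and the permutation test a list against no change between the regions, not against other genes, so they answer another question than camera. The published work behind the 2 regional lists may include work on these samples, so their direction is not independent evidence.

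The genes named were chosen by a rule fixed before the data were examined. It took the 12 genes per direction with the largest log2 difference past the threshold, 6 dopamine neuron genes whatever their p, the members of the regional lists past 0.05 adjusted over the list alone, and the 3 members of every other list with the smallest p. Genes named outside this rule are said to be so.

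The procedure was tested on simulated data with the real means and spreads of the 5244 probe sets, with 50 probe sets changed at each size. It recovered 30% of those changed by a log2 difference of 0.5, 80% at 1, 98% at 1.5 and 100% at 2. It made 7 calls among the unchanged probe sets, and 0 calls when none was changed. The values were drawn independently for each probe set and array, without correlation between genes or shifts of whole arrays. These counts therefore do not give the error rate in the real data.

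The alternatives fixed before the data were examined were quantile normalization, median centring, offsets of 1 and 64, no filter and a filter of 60%, the replicate number as a fixed or a random block, array weights, a trended and robust variance, thresholds of 0.01 and 0.10, an exact Wilcoxon test, the mean of all probe sets of a gene, and leaving out each array in turn. Fits without an array kept the filter and the representative probe sets of all 15 arrays, as the design stated. A first version chose them anew, which was corrected after it gave Rps15 another probe set without SNc 7. Leaving out VTA 5 and VTA 8 together, which had the lowest correlations with the other arrays, and the 3' to 5' signal ratios of the actin and GAPDH control probe sets as covariates were added after seeing the data. Group differences in single measures were tested by exact permutation over all 6435 splits of the arrays, two-sided.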

Results

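The data were gene expression profiles of neurons laser-captured from 2 neighbouring regions of the rat midbrain. The SNc holds the dopamine neurons that project to the dorsal striatum, and the VTA those that project mainly to ventral striatum and cortex. The series is titled for Parkinson's disease, in which SNc dopamine neurons are lost more heavily than those of the VTA, and the comparison asks how the neurons of both regions differ. There were 8 SNc and 7 VTA arrays. Median signal per array lay between 38.0 and 46.8, and the number of probe sets with a signal over 100 between 2700 and 2885. The highest correlation between any pair of arrays was 0.973, so no 2 arrays held the same values. VTA 5 and VTA 8 had the lowest median correlations with the other arrays, at 0.938 and 0.945. The first principal component held 16.9% of the variance and separated the regions (exact permutation p = 0.000777), with SNc 5, SNc 7 and SNc 8 nearest to the VTA arrays.

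Captures of both regions had high signals for genes of dopamine synthesis and uptake, and the regions differed in a small share of the genes tested. Pmepa1, Eno3 and Gad1 were among the genes higher in SNc, and Fst, Crhbp and Ntf3 among those higher in VTA. Of 5244 probe sets tested, 104 passed the threshold, 44 with higher signal in SNc and 60 with higher signal in VTA. These stood for 70 genes by their representative probe set, 32 higher in SNc and 38 higher in VTA. A difference of 2-fold or more was seen in 50 of the 104 probe sets, 20 higher in SNc and 30 higher in VTA. The SNc and VTA arrays did not overlap at all in 45 of the 5244 probe sets tested, where chance gives that separation to 0.031%, or 1.6 probe sets. Of the 45, 40 were among the 104. The share of calls that were higher in SNc was 42.3%, and 64.4% when each array was centred on its median, with 67 probe sets higher in SNc and 37 higher in VTA. The total of 104 moved by over 1.5 times on leaving out any of 8 single arrays. It was 69 without SNc 2, 56 without SNc 3, 68 without SNc 4, 66 without VTA 1, 59 without VTA 2, 68 without VTA 3, 62 without VTA 5 and 64 without VTA 6.

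Among the genes higher in SNc, Pmepa1, an inhibitor of TGF-beta signalling, had the clearest separation, with a signal of 2714 ± 538.5 in SNc and 764.5 ± 172.8 in VTA (log2 difference 1.81, SE 0.17, adjusted p = 3.44e-06). Prkcd, a protein kinase C isoform, was 2.27-fold higher (adjusted p = 0.000208), by both of its probe sets. Gad1, the enzyme that makes GABA, was 2.74-fold higher at 753.5 ± 179.9 against 279.1 ± 123.1 (adjusted p = 0.00154). Eno3, the muscle-type enolase of glycolysis, was higher by a log2 difference of 1.95, at a low signal of 169.9 ± 71.6 against 32.25 ± 19.25 (adjusted p = 0.000836). Sncg, or gamma-synuclein, was 2.07-fold higher (adjusted p = 0.00293) and lay at 1700 ± 364.8 in SNc. Fbxo21, a component of a ubiquitin ligase, was higher by 1.15 on the log2 scale (adjusted p = 0.00513), with a VTA mean of 21.23, below 26.3. Over the alternatives the difference ran from 1.24 to 2.52 for Eno3 and from 0.599 to 1.70 for Fbxo21. Each of these genes was higher in all 8 SNc arrays than the VTA mean.

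The other genes in the upper part of the SNc list were less firm. Igf1, insulin-like growth factor, had the largest difference of these genes, 4.01-fold (SE 0.38 on the log2 scale, adjusted p = 0.00676), but its 2 other probe sets gave -0.23 and -0.30, and neither passed. Nefh, the heavy neurofilament chain, was 2.12-fold higher (adjusted p = 0.0153), while its dimmer probe set gave 0.17. With the mean of all probe sets of a gene, the log2 difference was 0.492 for Igf1 and 0.626 for Nefh (adjusted p = 0.167 and 0.116). Pvalb, the calcium buffer of fast-spiking neurons, was 2.53-fold higher (adjusted p = 0.0282), and Kcnc1, a fast potassium channel of the same neurons, 2.15-fold (adjusted p = 0.0299). Rab3c, a vesicle GTPase, and Syne1, a protein of the nuclear envelope, were higher by 1.19 and 1.07 on the log2 scale (adjusted p = 0.0487 and 0.034), with Syne1 at 25.67 in VTA. Over the alternatives the differences ran from 0.838 to 1.75 for Pvalb, 0.768 to 1.47 for Rab3c and 0.624 to 1.42 for Syne1. The calls of Pvalb, Kcnc1, Rab3c and Syne1 were lost on leaving out any of 4, 6, 13 and 9 single arrays, with adjusted p up to 0.0573, 0.0677, 0.108 and 0.0753.

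Of the genes higher in VTA, Fst and Crhbp had the largest log2 differences. Fst, follistatin, which binds activin, had a signal of 10.78 ± 4.281 in SNc, below the 26.3 under which probe sets were left out by their mean, and 110.4 ± 49.44 in VTA (log2 difference -2.14, SE 0.23, adjusted p = 2.02e-05). Crhbp, which binds corticotropin-releasing hormone, was 4.02-fold higher in VTA (adjusted p = 0.00137), and Crh, the hormone itself, was also higher (log2 difference -1.30, adjusted p = 0.0322). Ntf3, a neurotrophin, was 2.65-fold higher at 631.6 ± 128.4 against 236.3 ± 78.03 (adjusted p = 0.00073). Olfm1, a secreted olfactomedin, was 2.38-fold higher (adjusted p = 0.000836). Serping1, an inhibitor of complement proteases, and Efemp1, a matrix protein, were higher by log2 differences of -1.33 and -1.20 (adjusted p = 0.0091 and 0.039). Crh and Efemp1, like Fst, had mean signals in SNc below 26.3, at 20.45 and 14.98, so the sizes of their differences depend on the offset. Over the alternatives the log2 difference ran from -3.16 to -1.17 for Fst, -1.83 to -0.715 for Crh, -1.40 to -0.609 for Efemp1 and -1.93 to -0.731 for Serping1. Both probe sets of Fst, Crhbp, Ntf3 and Olfm1 passed the threshold.

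Receptors, a potassium channel, a cyclin and an enzyme made up the rest of the upper VTA genes. Kcnj5, a G protein-gated potassium channel, and Ccnd2, a D-type cyclin, were higher in VTA, with log2 differences of -1.53 and -1.49 (adjusted p = 0.00217 and 0.00188). Htr7, a serotonin receptor, and Adrb3, a beta-adrenergic receptor, were higher by log2 differences of -1.44 and -1.53 (adjusted p = 0.012 and 0.0366). Kcnj5 and Htr7 had mean signals in SNc below 26.3, at 23.75 and 18.11. Over the alternatives their log2 differences ran from -2.25 to -0.84 and from -2.25 to -0.758, and that of Adrb3 from -2.13 to -0.881. Adrb3 was uneven within SNc, at 6.871, 6.945 and 7.087 in SNc 5, SNc 7 and SNc 8 on the log2(signal + 16) scale, against 4.633 to 4.989 in the other SNc arrays and 6.993 to 7.468 in VTA. Gch1, which makes the cofactor of tyrosine hydroxylase, was 2.53-fold higher at 1153 ± 290.6 against 463.3 ± 168.9 (adjusted p = 0.00163). Of its 3 probe sets, 2 passed. The calls of Crh, Efemp1 and Adrb3 were lost on leaving out any of 9, 11 and 11 single arrays, with adjusted p up to 0.073, 0.0828 and 0.0827. The probe set with the smallest p of all, M31176mRNA#2_at, is unnamed here. Given after its values were seen, it was 357.5 in VTA and 41.29 in SNc on average (log2 difference -2.69, adjusted p = 1.1e-06).

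**Figure D1:**
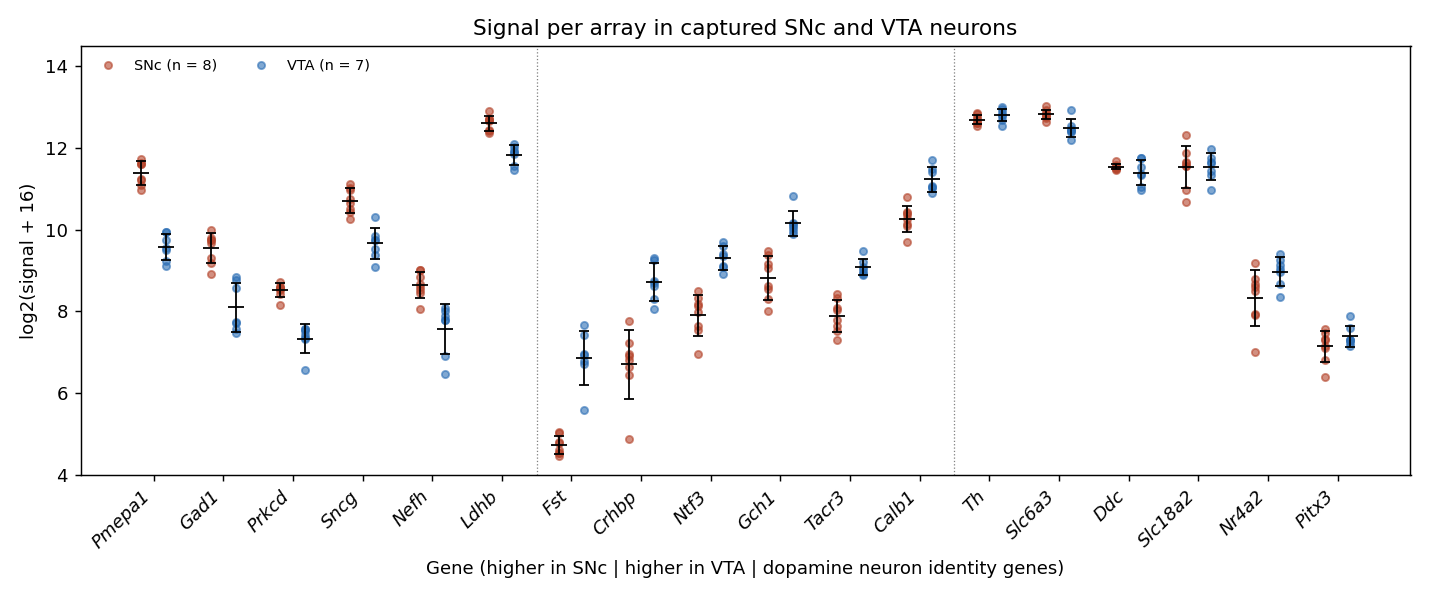
Each point is 1 array, as log2(signal + 16) on the vertical axis, for SNc (n = 8) and VTA (n = 7), and bars are mean ± SD. Pmepa1 was at least 10.972 in the SNc arrays and at most 9.953 in the VTA arrays, while Th and Ddc overlapped between the regions.

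Of the 6 dopamine neuron genes chosen in advance, 0 passed the threshold in limma, and 2, Slc6a3 and Nr4a2, had an unadjusted p under 0.05. Th, tyrosine hydroxylase, had a signal of 6615 ± 527.2 in SNc and 7193 ± 769.7 in VTA (log2 difference -0.12, SE 0.12, adjusted p = 0.67). Ddc, the next enzyme of dopamine synthesis, differed by 0.15 (SE 0.14), and Slc18a2, the vesicular monoamine transporter, by 0.00 (SE 0.21). Slc6a3, the dopamine transporter, was 7245 ± 602.7 in SNc and 5782 ± 978.8 in VTA (log2 difference 0.34, adjusted p = 0.193). The transcription factors Nr4a2 and Pitx3 differed by -0.65 and -0.25 (adjusted p = 0.228 and 0.538). Of 13 identity genes tested, 1, Gch1, passed, over all genes and adjusted over the list alone. The list's mean difference was -0.08, its median 0.02, and camera placed it higher in SNc than other genes (adjusted p = 0.805), so these differ in sign.

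Genes reported as enriched in SNc were higher there as a group. Of 9 members tested, 7 were positive and 2 negative, and 2, Igf1 and Rab3c, passed over all genes, and 5 adjusted over the list alone. The other 3 were Atp2a3, a calcium pump of the endoplasmic reticulum (0.85, SE 0.25), Fgf1, a growth factor (0.63, SE 0.25), and Slc6a3. The list's mean difference was 0.53 (camera adjusted p = 0.00158, and adjusted p = 0.0491 with an estimated correlation), and 0.327 with the mean of all probe sets of a gene. The list shares 4 tested members with the identity list. Without SNc 1, SNc 5, VTA 2 or VTA 3, 3 members passed over the list alone.

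Of 9 genes reported as enriched in VTA, 2 passed over all genes. These were Tacr3, a tachykinin receptor, with 531.8 ± 83 in VTA and 229.8 ± 66.05 in SNc (adjusted p = 0.000684), and Calb1, the calcium buffer calbindin, with 2440 ± 530.5 and 1248 ± 273 (adjusted p = 0.00302). Adjusted over the list alone, 3 were higher in VTA, with Lpl, lipoprotein lipase, as the third (-1.32, SE 0.35). Calb2, the calcium buffer calretinin, was higher in SNc over the list alone (0.61, SE 0.22). The list's mean difference was -0.36 and missed the threshold (camera adjusted p = 0.0822). It passed in 9 of 32 alternatives, among them leaving out SNc 3, SNc 8 or VTA 8, and missed with an estimated correlation (adjusted p = 0.224), with an adjusted p from 0.0172 to 0.261 over all 32. The 9 include the exact permutation of list means (adjusted p = 0.0361) and fry (adjusted p = 0.0187), which test against no change, not against other genes.

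Glycolytic enzymes were higher in SNc. All 11 genes tested had a positive difference, with a mean of 0.28 (camera adjusted p = 0.000988, and adjusted p = 0.0491 with an estimated correlation). Ldhb, the lactate dehydrogenase subunit, passed over all genes, at 6290 in SNc against 3677 in VTA (log2 difference 0.78, SE 0.14, adjusted p = 0.00313). Pkm, pyruvate kinase, joined it adjusted over the list alone, for 2 in all (0.60, SE 0.17), and Eno1, enolase, differed by 0.30 (SE 0.13). The oxidative phosphorylation list was higher in SNc by a small amount, with 42 of 52 positive and a mean of 0.10 (camera adjusted p = 0.00265), or 0.196 after median centring. That call was lost with an estimated correlation (adjusted p = 0.158), after quantile normalization (adjusted p = 0.161), and without VTA 4 (mean 0.07, adjusted p = 0.0581). None of the 52 passed in limma over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05. Among the list's members, the smallest p values were those of Atp5pf (0.46, SE 0.14), Uqcrfs1 (0.38, SE 0.14) and Ndufa4l2 (-0.41, SE 0.16). A dimmer probe set of Ndufa4l2 gave -0.11.

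These shifts lie beside a difference in the signal distributions. Median signal was 41.4 ± 3.04 in SNc and 45.1 ± 1.74 in VTA (n = 8 and 7, exact permutation p = 0.016, adjusted over 8 measures 0.0427). With the genes split by signal into 10 groups of 322 or 323, the median log2 difference was 0.0959 in the brightest group and -0.100 in the dimmest. The signal of the 3' GAPDH control, itself a glycolytic enzyme, was 5122 ± 986.6 in SNc and 3769 ± 498.8 in VTA (exact permutation p = 0.00435, adjusted 0.0348). The 3' to 5' ratios of the actin and GAPDH controls, which follow RNA integrity, did not pass between regions (exact permutation p = 0.212 and 0.571). The actin ratio was 9.94 ± 2.85 in SNc and 8.43 ± 0.82 in VTA, and the GAPDH ratio 4.335 ± 0.65 and 4.64 ± 1.27. Over all arrays they ran from 6.14 to 15.4 and from 2.94 to 6.82, so 3' signal exceeded 5' signal on every array. The lack of a group difference therefore does not show that the RNA was intact.

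**Figure D2:**
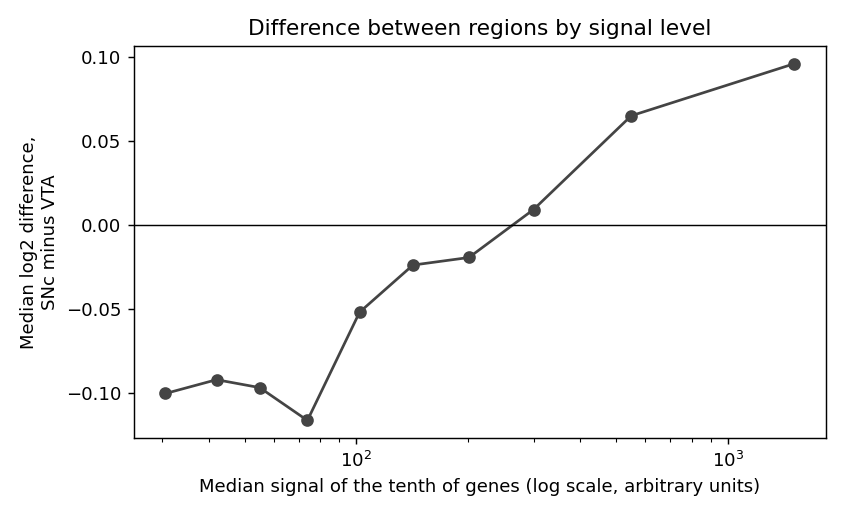
The horizontal axis gives the median signal of each of 10 groups of genes, on a log scale, and the vertical axis the median log2 difference, SNc minus VTA, of the genes in it. The medians go from -0.100 in the dimmest group to 0.0959 in the brightest.

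Neuropeptides and granins, the proteins of large secretory vesicles, were lower in SNc. Of 17 tested, 13 had a negative difference, with a mean of -0.30 (camera adjusted p = 0.0425). The call was lost with an estimated correlation (adjusted p = 0.224) and on leaving out any of 6 single arrays, SNc 2, SNc 4, SNc 7, VTA 1, VTA 4 or VTA 5 (adjusted p up to 0.11). Over all genes 3 passed, each higher in VTA: Crh, Scg2 at 1922 against 1177 (-0.73, SE 0.17) and Vgf at 203 against 114.7 (-0.80, SE 0.19). Adjusted over the list alone, 4 were higher in VTA and 1 higher in SNc. Those beyond the 3, named here after their values were seen, were Pcsk2 (-0.60, SE 0.19) and Chgb (0.48, SE 0.14). Leaving out any of 5 single arrays ended the call of Scg2 and any of 10 that of Vgf, with adjusted p up to 0.0673 and 0.0811. Adcyap1, a peptide named here after its values were seen, differed by -0.46 by its representative probe set, and by -1.45 and -1.15 by the 2 others, which passed.

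Immediate early genes, which neuronal activity and tissue handling induce, were lower in SNc, with all 10 tested negative and a mean of -0.33 (camera adjusted p = 0.00982). The call was lost with an estimated correlation (adjusted p = 0.185) and with the mean of all probe sets of a gene (adjusted p = 0.0568), and the mean was -0.214 with an offset of 64. None of the 10 passed in limma over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. They were Junb (-0.56, SE 0.20), Jun (-0.62, SE 0.26) and Egr1 (-0.40, SE 0.18), all at low signals, from 27.15 to 148.3.

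The lists of excitability and transmission missed the threshold with camera at its preset correlation. The synaptic vesicle cycle list, with 18 of 28 positive, had a mean of 0.12 (camera adjusted p = 0.0563). It passed in 13 of 32 alternatives, among them leaving out SNc 1, SNc 3, SNc 5, SNc 7 or VTA 8, and missed with an estimated correlation (adjusted p = 0.185). The 13 include the exact permutation (adjusted p = 0.021) and fry (adjusted p = 0.042), which do not compare the list with other genes. Rab3c passed, while Synj1 and Syn2 differed by 0.50 and 0.58. Of 39 voltage-gated ion channels, 1 was higher in SNc, Kcnc1, and 1 higher in VTA, Scn9a, a sodium channel (-0.73, SE 0.17, adjusted p = 0.028). Leaving out any of 6 single arrays ended the call of Scn9a, with adjusted p up to 0.0635. Cacna2d1, a calcium channel subunit, differed by -0.58 (adjusted p = 0.126). The channel list's mean was -0.01 and its median 0.002, and camera placed it up (adjusted p = 0.805). Of 29 glutamate and GABA receptor genes 0 passed in limma, and 6 had an unadjusted p under 0.05, with Gria1 (0.73), Grin2a (-0.66) and Grin2c (0.46) first. A second probe set of Grin2c passed, at 1.07. That list's mean was 0.003 and its median -0.008 (adjusted p = 0.723). Among 10 calcium-binding proteins Pvalb was higher in SNc and Calb1 in VTA, with Calb2 joining Pvalb over the list alone, and the list's mean was 0.08 with a median of -0.07 (adjusted p = 0.805). Axon guidance genes, with Slit1, Ephb1 and Unc5b at -0.34, -0.32 and -0.10, had a mean of -0.13 (adjusted p = 0.567).

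The 4 parkinsonism genes tested had a mean of 0.22, and the list missed the threshold (camera adjusted p = 0.0895), though it passed in 3 of 32 alternatives. These were a filter of 60%, and fry (adjusted p = 0.00666) and the exact permutation (adjusted p = 0.0129), which test against no change only. In limma 0 passed over all genes, and all 4 had an unadjusted p under 0.05. Adjusted over the list alone all 4 passed. Synj1 (0.50), Uchl1 (0.42, 3642 against 2698) and Park7 (0.43) were higher in SNc, and Pla2g6 (-0.49) in VTA. Park7, the list's remaining member, is named outside the rule, after its value was seen. Among 20 antioxidant and metal handling genes, 1 passed over all genes, Gpx3, a glutathione peroxidase higher in VTA (-0.63, SE 0.16), and 2 over the list alone, with Gstm1 (-0.66, SE 0.19). Cat, catalase, differed by -0.51 by its representative probe set while a dimmer one passed, at -0.66, and the list's mean was -0.09 (adjusted p = 0.599). Leaving out any of 11 single arrays ended the call of Gpx3, with adjusted p up to 0.0886. Of 12 heat shock genes and chaperones, Hspb1 was higher in VTA over the list alone (-0.63, SE 0.17), while its 3 other probe sets gave -0.77, -0.41 and 0.20. Hsph1 and Hspe1 differed by 0.38 and 0.33, and the list's mean was -0.07 (adjusted p = 0.723). Proteasome subunits had a mean of 0.04 (adjusted p = 0.179), with Psmc3, Psmb2 and Psmb8 at 0.53, 0.24 and -0.53. Cytosolic ribosomal proteins had a mean of -0.06 (adjusted p = 0.599), and passed in 1 of 32 alternatives, quantile normalization (adjusted p = 0.0269). Rps15 passed, higher in VTA (-0.66, SE 0.15), though its 2 other probe sets gave -0.38 and -0.004, and its call was lost on leaving out any of 5 single arrays, with adjusted p up to 0.0623, and with the mean of all probe sets (adjusted p = 0.106). Rpl18 and Rpl27a differed by -0.31 and -0.35.

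Of the markers of other cells, those of GABA neurons were higher in SNc. All 4 tested were positive with a mean of 0.77 (camera adjusted p = 0.00265, and adjusted p = 0.0491 with an estimated correlation), or 0.446 with an offset of 64. This rested on Gad1 and Pvalb, the 2 that passed, over all genes and over the list alone. Gad2, the second GABA-making enzyme, was at 62.63 against 47.14 (0.23, SE 0.26), and Slc32a1, the vesicular GABA transporter, at 403.2 against 373.9 (0.07, SE 0.18). Slc32a1, the list's remaining member, is named outside the rule, after its value was seen. The 5 markers of serotonin, noradrenaline and cholinergic neurons were all negative with a mean of -0.28 (adjusted p = 0.0563). The list passed in 7 of 32 alternatives, among them leaving out SNc 5, SNc 6 or VTA 3, with adjusted p down to 0.0207. It missed with an estimated correlation (adjusted p = 0.25). The 7 include fry (adjusted p = 0.033) and the exact permutation (adjusted p = 0.021), which test against no change only. The smallest p values were those of Fev (-0.41), Slc6a4 (-0.28) and Slc6a2 (-0.24). For glutamate neuron markers, 0 members could be tested.

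RNA of oligodendrocytes was abundant in both regions. Mbp, a myelin protein gene, had a signal of 3784 in SNc and 4838 in VTA (-0.36, SE 0.18), Mobp 2168 and 3064 (-0.53, SE 0.22), and Ugt8 differed by -0.35. The list's mean was -0.20 (adjusted p = 0.212). Astrocyte markers had a mean of -0.16 (adjusted p = 0.623), with Aqp4, Aldh1l1 and Slc1a2 at -0.60, -0.44 and -0.30. Microglia markers had a mean of -0.04 (adjusted p = 0.815), with Ctss, Cx3cr1 and C1qc at 0.25, -0.21 and -0.11. Vascular and blood markers had a mean of -0.19 (adjusted p = 0.567), with Alas2, Hbb and Pdgfrb at -0.32, -0.73 and 0.23. In these 4 lists 0 genes passed in limma over all genes or over the list alone, and 1 of them, Mobp, had an unadjusted p under 0.05.

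**Figure D3:**
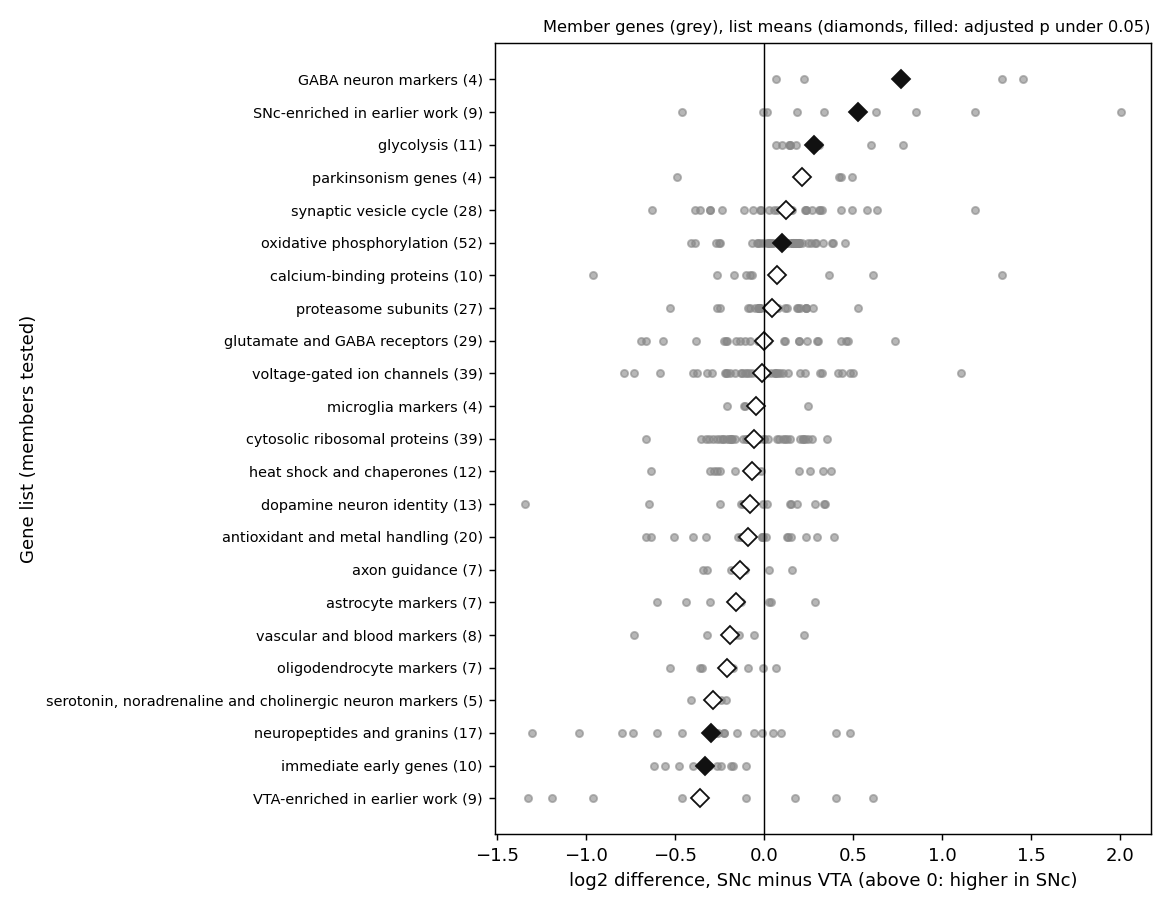
Grey points are the log2 differences, SNc minus VTA, of the tested members of each list, and diamonds their mean, filled where camera's adjusted p was under 0.05. The means run from 0.77 for GABA neuron markers to -0.36 for the list enriched in VTA.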

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

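The search for arrays far from the rest of their group was set before the data were examined, and no test of a cause was run on its results. In a group of 7 or 8 arrays, the gap of an array to the nearest other was divided by the range of the group. An array was singled out when that share exceeded Dixon's 95% critical value. Of 232 groups of values, 16 had such an array, and chance gives about 1 in 20 groups, or 11.6. Values are log2(signal + 16), and for lists the mean of the members.

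Among genes higher in SNc, Prkcd was 6.572 in VTA 5, where the next array had 7.323. Among genes higher in VTA, Crhbp was 4.872 in SNc 5 (next 6.44), Ccnd2 7.514 in VTA 8 (next 8.629) and Gch1 10.821 in VTA 8 (next 10.171). Crh stood apart in both groups, at 6.234 in SNc 1 (next 5.259) and 4.668 in VTA 8 (next 6.076). Scn9a was 6.881 in SNc 5 (next 6.249). Among genes that did not pass over all genes, Calb2 was 10.444 in VTA 4, Ndufa4l2 7.774 in SNc 7, Hspb1 8.393 in VTA 5, Ugt8 10.252 in VTA 3 and Slc6a2 6.111 in VTA 3. The nearest arrays had 9.794, 7.188, 8.822, 9.613 and 6.544. Among lists, voltage-gated ion channels were 7.024 in SNc 1 (next 6.892), microglia markers 7.309 in VTA 3 (next 7.124), vascular and blood markers 7.542 in SNc 5 (next 6.854), and serotonin, noradrenaline and cholinergic neuron markers 6.054 in SNc 3 (next 6.518).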

How the results depend on the processing

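Leaving out VTA 5 and VTA 8 together and the actin and GAPDH ratios as covariates were chosen after seeing the data. No result past the threshold turned its direction under any alternative run, and each of the 104 probe sets kept its sign wherever it was tested. The lists of SNc-enriched genes, glycolysis and GABA neuron markers stayed past the threshold in all 32 alternatives, with means of 0.327 to 0.631, 0.229 to 0.372 and 0.446 to 0.953. Of 919 combinations of the 32 called named genes with an alternative, 774 kept the call, 145 lost it and 0 reversed. Of these genes, 18 were called under each of the counted alternatives that tested them. Of the 18, Fbxo21, Fst, Kcnj5, Htr7 and Serping1 were tested in 28 alternatives and the others in 29. The gene and list counts given here leave out the other thresholds and the exact Wilcoxon test. Htr7, among the 18, had an adjusted p of 0.012 in limma, so it misses a threshold of 0.01. Of the 104 probe sets, 40 passed at 0.01 and 55 passed the exact Wilcoxon test. For the 17 lists not called, 489 of 543 combinations gave the same outcome, 33 passed the threshold and 21 had the other sign. The 33 were 13 of the synaptic vesicle cycle, 9 of the VTA-enriched genes, 7 of serotonin, noradrenaline and cholinergic neuron markers, 3 of parkinsonism genes and 1 of cytosolic ribosomal proteins. Low signal limits the dim genes, whose differences depend on the offset.

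The count of 104 probe sets, 44 higher in SNc and 60 in VTA, became 59 (25 and 34) with an offset of 1, where dim probe sets vary more, and 184 (70 and 114) with array weights. Median centring, which sets array medians equal, gave 67 higher in SNc and 37 in VTA. The exact Wilcoxon test called 67 (33 and 34). Thresholds of 0.10 and 0.01 gave 208 (87 and 121) and 40 (19 and 21). Without VTA 5 and VTA 8, 80 were called (28 and 52), and with the actin ratio as a covariate 65 were called (26 and 39). Leaving out 1 array gave 56 to 115 in all, 23 to 46 higher in SNc and 33 to 69 higher in VTA. The cause was not tested where the construction does not give it.

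The oxidative phosphorylation list lost its call after quantile normalization (mean 0.0677, adjusted p = 0.161), with an estimated correlation (0.104, 0.158) and without VTA 4, with means of 0.0739 to 0.124 over single arrays left out. Its adjusted p ranged from 0.000493 to 0.161. Neuropeptides and granins lost theirs with an offset of 1 (-0.355, adjusted p = 0.0522), no filter (-0.25, 0.0687), a filter of 60% (-0.236, 0.0587), array weights (-0.294, 0.0777), without VTA 5 and VTA 8 (-0.279, 0.16), with the GAPDH ratio (-0.295, 0.059) and an estimated correlation (-0.299, 0.224). Over single arrays left out their mean was -0.34 to -0.263, and over all alternatives the adjusted p 0.00961 to 0.224. Immediate early genes lost theirs with the mean of all probe sets (-0.251, adjusted p = 0.0568) and an estimated correlation (-0.332, 0.185), in a range from 0.00272. Of the SNc-enriched genes, 3 passed over the list alone with the actin ratio, and 3 to 5 over single arrays left out. The cause was not tested.

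With the replicate number as a replicate block, 99 probe sets were called (41 higher in SNc and 58 in VTA), 76 of the 104 among them. With the replicate block as a random effect, with a correlation of 0.121, 153 were called (62 and 91). Same-numbered arrays had correlations of 0.044 to 0.25 in their deviations from the group means, with a median of 0.11 against -0.026 for different numbers. All 7 same-number correlations were positive, and 5 of the 7 were over 0.1. As the labels name no shared animal or day, the main tests and permutations did not pair the arrays, and would ignore such a link. That 6 of 14 arrays correlated best with their own number is a hint of pairing from the data, not the design.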

Other observations

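The genes of the next paragraph, the makeup of the calcium and receptor families and the test of glial RNA were chosen after the results were seen.

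Other genes past the threshold are given singly, with no claim for a group. Maoa, a mitochondrial enzyme that breaks down monoamines, was higher in VTA by both probe sets past the threshold (-0.86 and -0.85). Slc25a5, which exchanges ADP and ATP across the mitochondrial membrane, was higher in SNc (0.71, SE 0.13), as were Slc25a11, an oxoglutarate carrier (0.56, SE 0.13), and Ckb, brain creatine kinase (0.53, SE 0.13). Gucy1b1, a subunit of the nitric oxide receptor, was higher in SNc (0.84, SE 0.15). Nefm, the medium neurofilament chain, was higher in VTA (-0.69, SE 0.18), opposite to Nefh. For Arpp21, a probe set passed, higher in SNc, at 159.4 ± 77.92 against 13.57 ± 15.79. That VTA mean lies below the filter level of 26.3, so no size is given. The representative probe set of Arpp21 gave -0.04.

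A chance assignment of these arrays to the regions was unlikely to give the count of probe sets. Shuffling arrays does not address chance differences between animals, as their number is not known. Of 100 splits of the arrays into 8 and 7, drawn from 6435, 1, the real one, called 104 or more. The highest other called 93. That split put 7 VTA arrays and 1 SNc array against the other 7 SNc arrays, so it is nearly the real one mirrored, and the next called 1. For lists past the threshold, 3 of the 100, the real one included, called as many as the real 6 or more. Among the 3 was the nearly mirrored split, which called 6 lists, and the highest other called 7. A share of 3 in 100 drawn splits is too imprecise to exclude chance at 0.05 for the count of lists. As 56 other splits called at least 1 list, a single list call at the preset correlation is weak evidence.

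Glycolysis and oxidative phosphorylation were higher in SNc, where bright genes also tended to be higher, and the call of oxidative phosphorylation was lost with an estimated correlation (adjusted p = 0.158) and after quantile normalization (adjusted p = 0.161). Among 10000 random lists matched on signal the glycolysis mean lay at percentile 99.33, which argues against the signal trend as its whole cause. The matched lists did not keep the correlation between members, estimated at 0.0739 for glycolysis, so that percentile is likely too extreme. Oxidative phosphorylation lay at 87.56, so the trend may account for that shift. With the actin ratio as a covariate the glycolysis and oxidative phosphorylation shifts kept 0.961 and 1.07 of their size and stayed past the threshold. As that ratio did not pass between regions (exact permutation p = 0.212), the adjustment had little room to change them. It therefore does not decide on RNA integrity. More glial RNA in the VTA captures cannot be told apart from a change in the neurons: relative to Th, Slc6a3, Slc18a2 and Ddc per array the lists differed by 0.189 and 0.0134 (8 and 7 arrays, exact permutation p = 0.111 and 0.884), while those 4 genes themselves differed by 0.0902 (exact permutation p = 0.301), so neither equal shifts nor a difference was shown. A difference between neurons of the regions stays open.

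The immediate early gene list, lower in SNc and made of dim genes, lay at percentile 1.04 of matched lists. Those lists did not keep the correlation between members, estimated at 0.146 here, so the percentile does not decide on the signal trend. The list's call was lost with an estimated correlation (adjusted p = 0.185). No test addressed tissue handling, and the biological difference between the regions stays open.

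Gad1 and Pvalb may have come from neighbouring GABA neurons taken along with the SNc captures. Across the 8 SNc arrays they had Pearson r = 0.513 (exact permutation p = 0.189, adjusted over 4 relations 0.681) and Spearman rho = 0.548 (exact permutation p = 0.171), and r was 0.137 without the 2 arrays farthest from the median. Gad1 had r = -0.0222 with Kcnc1, 0.273 with Nefh and -0.378 with Th (exact permutation p = 0.959, 0.511 and 0.349), rho of 0.143, 0.286 and -0.357, and r of -0.119, 0.709 and 0.153 without the 2 farthest arrays. As none of the 4 relations passed in either direction, a contribution of GABA neurons cannot be told apart from expression in the dopamine neurons. Slc32a1 and Gad2, which such neurons also express, differed by 0.07 and 0.23 without passing.

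A hypothesis was that calcium pumps and stores shifted as a family, from Itpr1 (0.93, adjusted p = 0.00217) and Atp2a2 (0.57, adjusted p = 0.0478), both higher in SNc. The rest of the family went both ways, with 5 of 9 members positive and a mean of 0.0441. Among them Atp2b2 gave 0.41 by its representative probe set, while another passed, at 1.30. Set against all other genes tested in limma, the rest had an adjusted p = 0.511 by camera over the 2 families, which leaves the hypothesis undecided. A second hypothesis was that receptors for transmitters and peptides shifted towards VTA, where 6 of 37 were called (Tacr3, Mc3r, Adra1b, Adrb3, Htr7 and Calcr), against 1 in SNc, Ntsr2. A gene that is not a receptor, Mcrs1, was taken out of the family after the first result. Bdkrb1, not called by its representative probe set at -0.49, stayed in, though another of its probe sets passed, at -1.30. As the family was built after its called members were seen, the rest is not an independent check. The 30 members left had a mean of -0.198, with 22 negative, at percentile 1.54 of matched lists (camera p = 0.00704, adjusted p = 0.0141 over the 2 families, and p = 0.165 with an estimated correlation). The mean was -0.124 after quantile normalization and -0.105 after median centring, so a family shift may be present, though the camera call was lost with the estimated correlation.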
